A study of Arabidopsis thaliana with 5 samples.

How the data were processed

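Gene expression was measured in whole seedlings of Arabidopsis thaliana, ecotype Col-0, grown for 14 days at 22 °C with 16 h of light per day, per the labels' protocols. The hypoxic seedlings were held in bags flushed with gas of 0.2% oxygen and 99.8% nitrogen for 30, 60 or 240 min, and the air samples were taken at 0 and 240 min. The series' design text calls the 5 samples independent. Each treatment and time has 1 array, so hypoxia is represented by 3 arrays and air by 2. In the text below, hypoxia replicates 1, 2 and 3 are the 30, 60 and 240 min arrays, and air replicates 1 and 2 are the 0 and 240 min arrays. These numbers only name the arrays and pair nothing.

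The deposited table holds log2 values for 8297 probe sets of an Affymetrix 1-colour array hybridised with biotin-labelled cRNA. The values were made with RMA, per the submitters' processing notes. The RMA software, its version and any step beyond it are not given in the sources used here. The medians of the 5 columns lay between 5.12 and 5.14, so the deposited values were used without further scaling in the main results. Probe-level signals and detection calls were not used here, and the number of arrays limits the precision. RMA subtracts a background and quantile-normalizes the arrays together, so that an artefact on 1 array can remain in its own column, and differences from or to the floor of about 4 to 5 are compressed and can only be lower bounds.

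The 50 control probe sets were set apart and 8247 were tested. A table of the platform's annotation listed 3864 probe sets, of which 3794 had 1 gene and 70 had several. The other 4433 are unnamed here. Of the probe sets with 1 gene, 3784 matched a locus in the TAIR10.1 RefSeq gene table, which was used for locus codes and symbols only, and 10 did not. In all, 3600 genes could be named, from 46.0% of the probe sets tested. No coordinates are given, because no source used here states a genome build for the probes.

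Hypoxia was compared with air by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with Benjamini-Hochberg adjustment and a threshold of 0.05). The times served as the replicates in that fit, so its spread holds both variation between samples and change with time. The 4 single-array comparisons (30 and 60 min of hypoxia against 0 min air, 240 min of hypoxia against 240 min air, and 240 min air against 0 min air) have no replicates and no p-value. They count probe sets that differ by 1 or more on the log2 scale (2-fold) and reach the array's median level in at least 1 of the arrays compared. The limma fit over 8247 probe sets was tried on simulated data with the residual spread of the 3 against 2 arrays, as moderated by eBayes. It recovered 86% of 100 probe sets shifted by 2 and 95% of 100 shifted by 4, with 17 false calls, more than the threshold aims at. With the spread of the 2 air arrays it recovered 100% of both, with 9 false calls. Each simulated shift was the same at all 3 times of hypoxia, so recovery of differences that change with time is not known.

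Before the data were examined, 17 gene lists with 345 genes were fixed. Only 32 of those genes were measured by a named probe set, and 4 lists (oxygen sensing and the N-degron pathway, root markers, jasmonate and wounding, and reference genes) had 0 measured members. The 2 lists with 5 or more measured members were tested with camera, with a preset correlation of 0.01. For the single-array comparisons, the median of each list with at least 3 members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these arrays. This gave 20 percentiles for fixed lists. A gene with several probe sets entered a list through the one with the highest mean. A further 4 lists were written after the values had been seen: class III peroxidases (46 measured of 74), root-expressed genes (2 of 69), photosynthesis and photorespiration (15 of 103), and dehydrins and LEA proteins (22 of 48). They gave 12 more percentiles, and a screen of 9 gene families by symbol gave 36.

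The rule for named genes was also fixed beforehand. It took the 10 genes most above and the 10 most below air in the limma comparison, the 4 largest differences each way in every single-array comparison, and the 3 members of each list with the largest mean difference. In the first part, places left empty by the adjusted p were filled at an unadjusted p under 0.05, for genes with every hypoxic array on one side of both air arrays. It also asked for 10 known low-oxygen genes (ADH1, PDC1, SUS1, SUS4, HB1, PCO1, PCO2, LBD41, HRE1 and HRE2), none of which was named by a probe set here. Further members of the small fixed lists, namely AT2G17850, WRKY6 and LHCB4.3, are given to complete their lists. Other genes outside the rule were chosen after their values were seen.

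After the values had been seen, a patch of probe sets was defined on the 240 min hypoxic array. Dim probe sets were those under 5.5 on the other 4 arrays. A probe set belongs to the patch when the median 240 min difference of its dim neighbours was at least 0.5. Its neighbours are those within 3 numbers on one side of it, together with those 33 numbers away (give or take 1) in either direction. Its own value does not enter, either side can qualify, and at least 3 neighbours are needed, so that a probe set with fewer counts as outside. In all, 3 definitions were tried in turn. The first pooled both sides and asked for 5 neighbours, and the second took each side on its own with 5. The third was kept because it also reached probe sets with few neighbours, and the counts under all of them are given. The kept definition, applied to the 30 and 60 min comparisons, found 27 and 5 probe sets.

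The alternatives fixed beforehand were quantile normalization again, median centring, a filter that drops the dimmest 25% of probe sets, eBayes with trend and robust settings, array weights, time as a covariate, each array left out in turn, other thresholds, the mean of both air arrays as control, no level filter, and, for the gene lists, an estimated correlation, fry, and other choices of probe sets. Leaving out the patch, other controls and scalings for the list medians, and the estimated correlation with each array left out, were added after the values had been seen. Figures were drawn with matplotlib 3.10.9.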

Results

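The study asks how gene expression in Arabidopsis seedlings differs after 30, 60 and 240 min in 0.2% oxygen from seedlings kept in air. The data are 5 arrays, 3 from hypoxic seedlings and 2 from air. With 1 array per treatment and time, single-array differences below carry no replicate error. The nearest yardstick is the pair of air arrays, whose differences had an SD of 0.27 on the log2 scale and whose values correlated at r = 0.99 across probe sets, which are not independent replicates.

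Among genes at an unadjusted p under 0.05 with every hypoxic array on one side of both air arrays, those most above air across all times included 3 dehydrins. LTI30, a dehydrin, was higher by 1.24 ± 0.38 (log2, SE, n = 3 against 2), AT1G54410, another dehydrin, by 1.16 ± 0.16, and COR47, a cold-regulated dehydrin, by 0.78 ± 0.20. The defensin gene LCR69 was higher by 1.003 ± 0.367 and the peroxidase gene AT2G37130 by 0.94 ± 0.29. The furthest below air among genes so selected was FIB, which encodes a fibrillin of plastid lipid bodies, at −1.08 ± 0.12. It was followed by AT4G29030 at −0.78 ± 0.25 and AT3G21670, of the nitrate transporter family, at −0.72 ± 0.23. The other genes taken by the rule were AT2G12400, AT2G23120, AT4G01000, AT4G14230 and AT2G25730, higher by 0.49 to 0.68. On the lower side they were AT4G15430, AT2G22730, AT4G27360, AT4G34630, AT4G32460, AT2G19650 and AT1G61890, at −0.68 to −0.58. Without the 240 min air array, AT4G15430 was at −0.42, AT4G34630 at −0.39 and AT2G22730 at −0.33. A second probe set of COR47 was higher at 30 min by 1.70 but lower at 240 min, at −0.37.

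None of these genes passed the test. By limma, 0 of 8247 probe sets reached an adjusted p under 0.05, and the lowest adjusted p was 0.98. At an unadjusted p under 0.05 there were 161 probe sets, 46 higher and 115 lower in hypoxia, where chance alone gives 412.4. Every hypoxic array lay above both air arrays for 5.2% of probe sets and below both for 8.16%, against 10% each way by chance. Without the 60 min array the count at an unadjusted p under 0.05 was 410, and without the 240 min hypoxic array it was 381, still with 0 passing the adjusted threshold.

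The largest differences after 30 min of hypoxia were single genes above 0 min air. AT4G33720, of the PR-1-like family, was higher by 5.11, with 4.47 at its second probe set. OSM34, an osmotin, was higher by 4.23, AT4G16260, of the β-1,3-glucanase family, by 3.96, and AT5G19890, a class III peroxidase, by 3.68. These 4 genes were near their air levels at 60 min except OSM34, which was higher by 1.15. The lowest were AT2G26690, of the nitrate transporter family, at −2.51, AT1G23130 at −1.79, and the Calvin cycle genes SBPASE at −1.70 and PRK at −1.68.

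All 4 measured members of the fixed list of photosynthesis genes, set as shoot markers, were lower at 30 min, with a median of −1.07 (percentile 0.77 of the random lists). PSAN was at −1.45, RCA, which encodes Rubisco activase, at −1.09, LHCB4.1 at −1.06 and LHCB4.3 at −0.29. After quantile normalization again the median was −0.59. A wider list of photosynthesis genes, written after the values had been seen, had 15 of 15 members lower, with a median of −1.06. It includes the 4 genes of the fixed list as well as SBPASE and PRK, so it is not independent of the values above. Of 46 class III peroxidases, also listed afterwards, 16 were higher by 1 or more and 0 were lower by as much. On the same array the ubiquitin and GAPDH control probe sets were higher by 1.51 to 1.78, and the actin control by 0.18. The non-plant BioB, BioC, BioDn and CreX controls (probe sets ending in _at) differed by −0.09 (BioB-5) to 0.75 (CreX-3).

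In numbers, 237 probe sets were higher and 242 lower by at least 1 at 30 min, or 10.5% of the 4555 at the level required. Air at 240 min against air at 0 min gave 15 and 10 of 4441, or 0.56%. The 30 min comparison has no time-matched air array, and a single array cannot separate treatment from the sample.

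**Figure D1:**
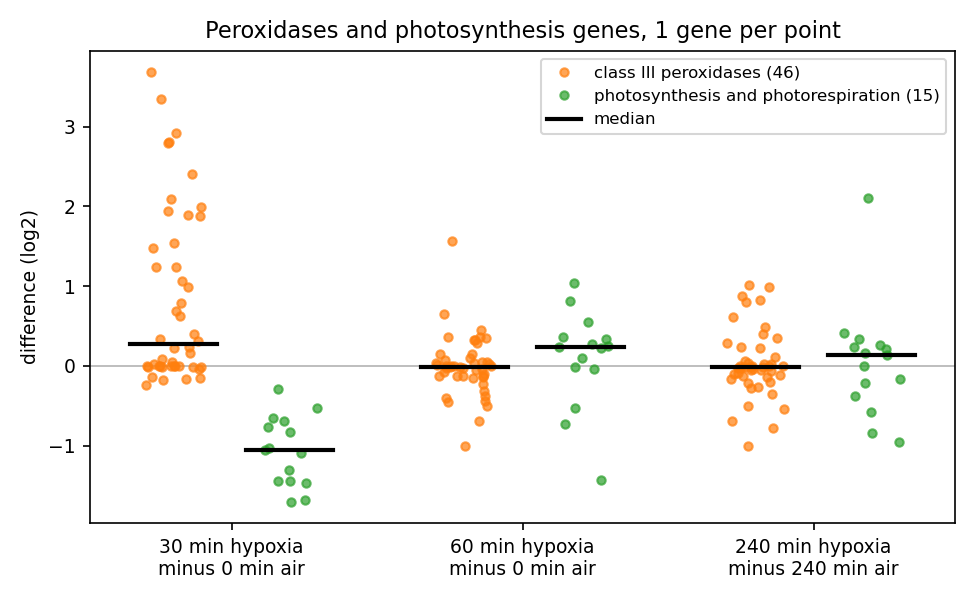
Differences from air (log2, vertical axis) at 3 times of hypoxia, 1 array per condition, for 46 class III peroxidases and 15 photosynthesis genes. Each point is a gene and each bar the median, which at 30 min was 0.28 for the peroxidases and −1.06 for the photosynthesis genes.

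After 60 min of hypoxia, the low-oxygen core genes were above 0 min air, led by AT4G27450, higher by 2.82. PDC2, which encodes a pyruvate decarboxylase of ethanolic fermentation, was higher by 2.07 and AT4G33560 by 1.18. AT2G17850 was higher by 0.85 and AT4G17670 differed by 0.01. Against the mean of both air arrays, PDC2 was higher by 1.49 and AT4G33560 by 0.51, and against 240 min air alone AT4G33560 differed by −0.15. The list's median was 1.18, above all of the random lists (percentile 100), and 5 of its 5 measured members were above 0. Outside the list, AT3G15450 was higher by 2.46, AT2G16586 by 2.36 and AT1G03220 by 2.103.

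The stress transcription factor WRKY53 was higher by 1.73 at 60 min, and STZ, a zinc finger repressor, by 0.80. WRKY22 was higher by 0.33 and WRKY6 by 0.01, and the median of these early stress genes was 0.57 (percentile 99.7). MCCA, a gene of leucine breakdown and the only measured sugar starvation gene, was higher by 1.93. AT3G09440, which encodes a cytosolic HSP70, was at −2.27, with −0.32 at its second probe set. AT2G21160 was at −1.63 and −1.61 at its probe sets, AT1G09310 at −1.64 and AT4G29020 at −1.46. In numbers, 106 probe sets were higher and 101 lower by at least 1, of 4477. Against the mean of both air arrays the low-oxygen median was 0.71, AT4G27450 was higher by 2.14, AT3G15450 by 1.89, AT2G16586 by 1.698 and AT1G03220 by 1.59, and AT3G09440 was at −1.64.

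At 240 min, 3 of the 5 low-oxygen genes were below time-matched air by 1 or more. AT4G33560 was at −3.99, reading 4.64 near the compressed floor, AT4G27450 at −3.56 and PDC2 at −1.48, and the list's median was −1.48 (percentile 0), with AT2G17850 at −0.44 and AT4G17670 at −0.07. AT1G03220 was at −3.68. Against the mean of both air arrays, AT4G33560 was at −3.33, AT1G03220 at −3.17, AT4G27450 at −2.88 and the list's median at −0.90. SAMDC, a gene of polyamine synthesis, was at −4.06 at the probe set the rule named but at −0.90 at a second, brighter one. The early stress list was at −0.54 (percentile 0.97), with STZ at −1.10 (0.16 at its second, dimmer probe set), WRKY6 at −0.63, WRKY22 at −0.46 and WRKY53 at −0.27. The cytosolic ribosomal protein genes had 6 of 6 members above 0 and a median of 0.50 (percentile 98.8), with AT1G70600 at 1.02, PGY2 at 0.61 and PGY1 at 0.01. At 60 min 5 of the 6 were below 0, with a median of −0.25 (percentile 10.2).

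The 4 genes named as most above air at 240 min were AT4G32350 at 4.14 (3.76 against the mean of both air arrays), TBL34 at 3.98, AT2G17650 at 3.75 and AT2G13350 at 3.74. Each read under 5.5 on the other 4 arrays, and each belongs to the patch of 713 probe sets whose dim neighbours by number were also higher on this array. Of the 454 probe sets higher by at least 1 at 240 min, 330 lie in the patch and 124 outside it. Under the 2 definitions tried earlier, 183 and 154 lie outside. Of the 165 that were lower, 160 lie outside. Outside the patch, chosen after their values were seen, AT2G45120 was higher by 2.73, AT4G00320 by 2.21, PORB, an enzyme gene of chlorophyll synthesis, by 2.11, CCL by 1.92 and LTI30 by 1.82. Hsp70-2 was higher by 1.84 but has too few dim neighbours to be judged. The 3′ GAPDH control probe set exceeded the 5′ one by 1.97 on this array, and by −0.23 to 0.69 on the other 4.

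**Figure D2:**
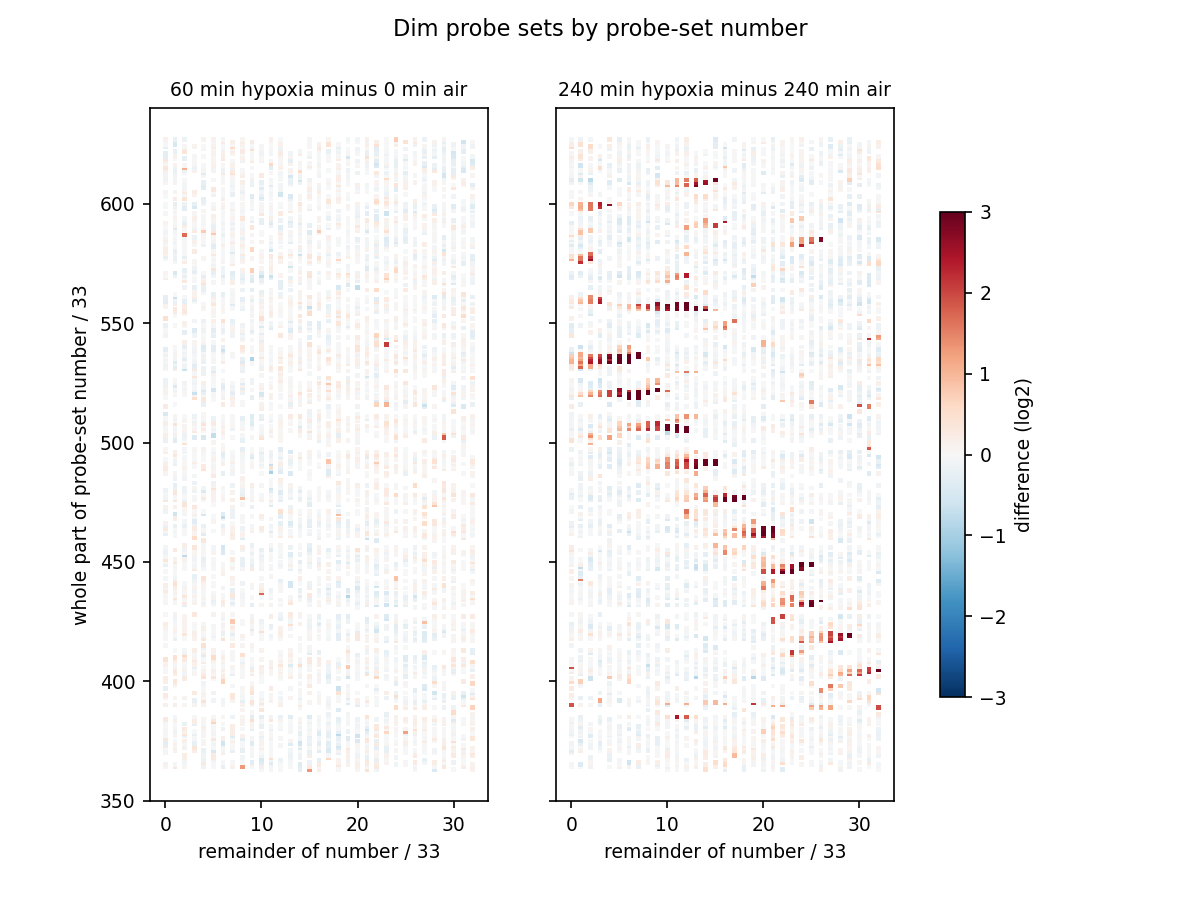
Dim probe sets (at 60 min, under 5.5 on both air arrays and the 30 min array; at 240 min, under 5.5 on the other 4 arrays) laid out by probe-set number folded at 33, with colour for the difference from air (log2). The 240 min panel shows runs of higher neighbours, where values 33 numbers apart correlated at 0.73; at 60 min that correlation was 0.19.

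In air, few probe sets differed between 240 and 0 min, and 3 of the 5 measured low-oxygen genes were among them. AT4G27450 was higher by 1.36, AT4G33560 by 1.33 and PDC2 by 1.16 after 240 min in air, while AT2G17850 differed by 0.29 and AT4G17670 by −0.11, with a list median of 1.16 (percentile 100). AT2G16586 was higher by 1.32 and AT4G32480 by 1.17. STOMAGEN, which encodes a peptide that promotes stomata, was at −1.84, AT3G09440 at −1.26, AT4G24340 at −1.06 (−0.40 at its second probe set) and the expansin gene EXPA8 at −0.92.

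Within hypoxia, the low-oxygen genes read highest on the 60 min array. AT4G27450 read 7.79, 11.81 and 6.79 at 30, 60 and 240 min, against 8.99 and 10.35 in air at 0 and 240 min. PDC2 read 5.62, 7.85 and 5.46, against 5.78 and 6.94. At 30 min the list's median difference was −0.25 from 0 min air and −0.74 from the mean of both air arrays. LTI30 read 5.64, 6.43 and 6.82, which is 0.52, 1.31 and 1.82 above the air arrays used as controls, and AT4G29020 read 10.06, 9.65 and 7.79, against 11.11 and 11.11. No error attaches to any of these time courses.

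**Figure D3:**
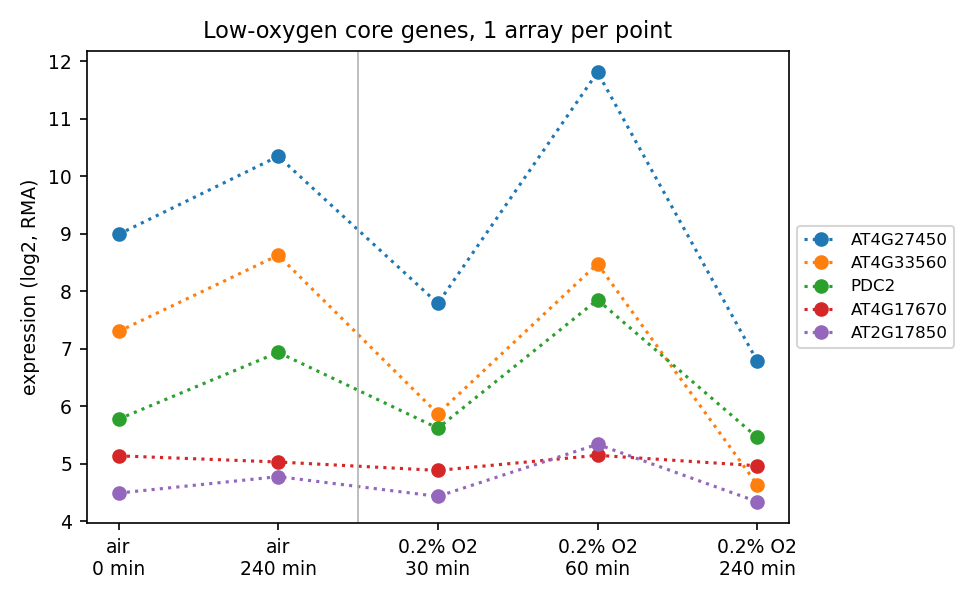
Expression (log2, vertical axis) of the 5 measured low-oxygen core genes on each of the 5 arrays, 1 point per gene and array. AT4G27450 spans 6.79 to 11.81, highest at 60 min of hypoxia and lowest at 240 min of hypoxia.

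Tested as groups across all times, neither list with enough members passed. The low-oxygen core genes had a mean difference of −0.51 and a median of −0.09 in 5 genes (camera in limma, adjusted p = 0.65; adjusted p = 0.92 with an estimated correlation). The cytosolic ribosomal protein genes had a mean of 0.02 in 6 genes (adjusted p = 0.85). Leaving out the 60 min array took the low-oxygen mean to −1.26 with a camera adjusted p of 0.000862 at the preset correlation. With an estimated correlation, a setting added after the values had been seen, the camera adjusted p without that array was 0.219. Over the other alternatives fixed beforehand the adjusted p ran from 0.28 to 0.98. Of the members of these 2 lists, 0 passed over all probe sets and 0 adjusted over the list alone.

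Of the remaining fixed lists, 4 had 0 measured members and the others had 1 to 4 and were not tested as groups. COR47, the only measured gene of the abscisic acid, cold and drought list, had a p of 0.0159 adjusted over the list alone by limma, which for 1 gene is the unadjusted p. In the fermentation and glycolysis list, the lactate dehydrogenase gene AT4G17260 differed by −0.16 and PDC2 by −0.05 between hypoxia and air. Of the heat shock genes, AT1G53540 differed by −0.12 and ATHSP22.0 by −0.03. The mitochondrial dysfunction gene AT2G21640 differed by 0.04, the ethylene signalling gene EIN3 by 0.06, the clock gene GI by −0.02 and the replication gene PRL by 0.37. Of the auxin and cell wall genes, EXPA8 differed by −0.57, GH3.3 by 0.28 and WES1 by 0.18.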

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

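All tests weighed in this part were chosen after the results had been seen. Genes are listed first where hypoxia and air differed in opposite directions at 60 and 240 min, with 1 array on each side, and the difference between the times was not tested. At 240 min AT4G33560 was at −3.99, AT1G03220 at −3.68, AT4G27450 at −3.56, AT3G15450 at −2.73 and PDC2 at −1.48 against air, each being higher at 60 min than 0 min air by 1 or more. For AT4G33560 this rests on the 0 min air array, as its 60 min value differed from 240 min air by −0.15. AT3G09440 went the other way, at 1.22 at 240 min after −2.27 at 60 min.

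For the low-oxygen genes that stood below air at 240 min, membership of the patch says little about the cause. Of the 5 measured members, 0 lie in it under any of the 3 definitions. The kept definition holds only 8.65% of the probe sets tested, so that few of them would lie in it by chance. Moreover, 2 of the 5, AT4G27450 among them, have too few dim neighbours to be judged. The patch was defined by raised values only, so a local defect that lowers values was not looked for and stays open. An exchange of the 240 min arrays stays open. The array labelled 240 min hypoxia differed from 0 min air by 1 or more at 285 probe sets outside the patch, and the array labelled 240 min air at 23. These counts cannot decide it, because the array labelled hypoxia also stands out in its control probe sets, whichever sample it holds. The array labelled air carries the low-oxygen genes at a median of 1.16 above 0 min air. Degraded RNA may contribute, as the 3′ GAPDH probe set exceeded the 5′ one by 1.97. For ubiquitin the excess of 2.39 was also the highest of the 5 arrays, though nearer to the 1.67 to 2.15 of the others. Where the other probes lie along their transcripts was not analysed here. A real decline of these transcripts by 240 min, a single wrong label and a change of the air control with time of day were not tested and remain possible.

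Mouse control probe sets read higher on the 240 min hypoxic array than on any other. IL4 was higher than at 240 min in air by 1.33, IL10 by 0.91, IL2 by 0.82 and FAS by 0.27, while 4 yeast controls differed by −0.10 to 0. The Arabidopsis 25S rRNA control was higher by 1.41 and the 5S rRNA control by 0.99, differences that were not tested and whose cause is open, and the GAPDH 3′ minus 5′ value of 1.97 was likewise the highest of the 5 arrays. Of 4697 dim probe sets, 303 were higher at 240 min by 1 or more and 0 were lower, though the floor left probe sets chosen under 5.5 little room to fall. Of the 303, 82.5% lie in the patch, which holds 10.1% of dim probe sets. The share was 72.9% and 75.9% under the earlier definitions. The patch was drawn from these same differences, so the shares restate the clustering by number and are not a separate test. Whether a response of these genes to hypoxia had a part stays open. A spatial defect of this array may account for the higher dim probe sets. Differences of probe sets 33 numbers apart correlated at 0.73, against at most 0.26 in the other comparisons. Physical positions were not analysed here, so that probe-set numbers stand in for them.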

How the results depend on the processing

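Across the alternatives that kept both air arrays, 0 probe sets passed an adjusted p under 0.05 (or 0.10) in hypoxia against air. All 228 recomputed differences of named genes kept their direction, which their selection largely fixed. Genes with every hypoxic array on one side of both air arrays cannot reverse when 1 array is left out, and the others were chosen for large differences. Of the single-array differences, 9 moved by more than the SD of the air pair against the mean of both air arrays. Without the 240 min air array, the hypoxia minus air differences of AT4G15430, AT4G34630 and AT2G22730 shrank by over 1.5 times, to −0.42, −0.39 and −0.33. The count at an unadjusted p under 0.05 was 243 with array weights, and leaving out 1 array at a time moved it between 178 and 410. With a difference of 1.5 in place of 1, which by construction counts fewer, the higher and lower counts were 120 and 65 at 30 min, 48 and 28 at 60 min, 283 and 62 at 240 min, and 2 and 4 in air. Leaving out the patch, an alternative added after the values had been seen, took the 454 higher probe sets at 240 min to 183, 154 and 124 under the definitions in the order tried. The mean difference of the low-oxygen core genes ran from −1.26 to −0.0198 with 1 array left out, and passed (camera, adjusted p = 0.000862) only without the 60 min array; with an estimated correlation, added after the values had been seen, it did not (camera, adjusted p = 0.219). That of the ribosomal protein genes ran from −0.16 to 0.16, turning negative at −0.0704 without the 240 min air array and at −0.16 without the 240 min hypoxic array. Against the mean of both air arrays, the low-oxygen medians were −0.74 at 30 min, 0.71 at 60 min and −0.90 at 240 min. Quantile normalization again took the 30 min median to −0.59 for the shoot markers and −0.73 for the wider photosynthesis list. For all but the thresholds, the cause was not tested. Where leaving out an array left 1 in air, that array was assumed to vary like the others. No paired analysis was possible because only 240 min has both a hypoxic and an air array. Without signal over background, the limit for dim genes is not known beyond the compressed floor.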

Other observations

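Several genes of dehydrins and late embryogenesis abundant proteins stood above air at more than 1 time, in a list written after the values had been seen. Of 22 measured, AT1G54410, LTI30, COR47 and AT2G23120 had an unadjusted p under 0.05 by limma. Adjusted over the list alone, 1 passed (AT1G54410, limma adjusted p = 0.0272), which is not independent evidence since that gene prompted the list. The list's median difference between hypoxia and air was 0.08. At single times its median was 0.02 at 30 min (percentile 71.1), 0.10 at 60 min (percentile 97.9, with 16 above 0 and 4 below) and 0.10 at 240 min (percentile 98.8, with 13 above 0 and 9 below). KIN2, a cold-induced gene, was at −0.79 at 30 min and 1.203 at 240 min, and COR15B, at 1.86 at 240 min, lies in the patch.

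In the screen of 9 families by symbol, the 7 measured WRKY genes had medians of 0.28 at 30 min (percentile 94.95) and −0.27 at 240 min (percentile 4.88), and the 20 UGT genes 0.14 (percentile 96.1) and −0.17 (percentile 3.76). The 7 NET genes had a median of 0.27 at 240 min (percentile 99.5), with 3 of them in the patch. The BGLU, GH, GLR, SCPL and TBL families lay between percentiles 6.17 and 90.0 in all 4 comparisons. With 36 percentiles computed, a few this far out are expected by chance.

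The tests in the rest of this part were chosen after the results had been seen, though the shoot marker list was fixed beforehand. Among peroxidases higher at 30 min, AT3G01190 was higher by 3.35, AT5G17820 by 2.93, AT5G64100 by 2.81 and AT2G38390 by 2.80. Scaling between arrays stays open. After quantile normalization again 16 peroxidases, the same ones, were higher by 1 or more. As RMA had already quantile-normalized the arrays together, a second pass is a weak check. A larger share of root tissue in the 30 min sample is a candidate explanation: the shoot markers, fixed beforehand, had a median of −1.07 at 30 min. After quantile normalization again that median, of 4 genes, was −0.59. Only 2 of the root-expressed genes listed were measured, BGLU21 higher by 1.60 and JAL31 by 0.42, and no fixed root marker was, so that the root side is nearly unmeasured. A transient response to 30 min of hypoxia cannot be told apart from this with 1 array per time; at 60 min 1 peroxidase was higher by 1 or more.

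Of the 10 ways to split the 5 arrays into 3 and 2, 7 gave at least as many probe sets at an unadjusted p under 0.05 as the real split. The real count was 161 and the highest of the others 578, with the 30 and 240 min hypoxic arrays set against the rest. With 10 splits no share under 0.05 can be reached. That split gives several times the real count, where chance alone gives 412.4. It was picked as the highest, and a structure of the samples was not tested. The other 3 arrays correlated with each other at 0.97 to 0.99, and these 2 with each other at 0.89, less than any other pair.

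One hypothesis was that the difference at 60 min partly repeats a change over the experiment that is not specific to hypoxia, because AT4G27450, PDC2 and AT3G15450 were also higher in air at 240 min. Across 2024 brighter probe sets outside the patch, the difference between 60 and 30 min of hypoxia correlated at 0.18 with that between 240 and 0 min of air, pairs with no array in common, and that between 60 and 240 min of hypoxia correlated with it at 0.26. Of 237 probe sets higher by 1 or more at 60 than at 30 min, 129 were above 0 in air, and of 205 lower, 98 were below 0. These values leave the question open. The 30 and 240 min hypoxic arrays subtracted here differed from air at more probe sets than the 60 min array. Their own differences therefore enter the correlations and counts and can hide a shared change.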
